A study of Mus musculus with 384 samples.

How the data were processed

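Single hair follicle stem cells from mouse back skin were sorted into 96-well plates, reverse transcribed and amplified by Smart-seq2, tagmented with a Nextera XT kit and sequenced in paired-end mode on a NextSeq instrument, per the labels' protocols. Smart-seq2 reads whole transcripts, carries no molecular identifiers and does not mark strand. Reads from antisense or overlapping genes cannot be told apart, and amplification copies are counted with the molecules they come from.

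The deposited table holds TPM (the share of a gene among transcripts, scaled to a fixed total), per its values: each column sums to that total over 46609 rows, of which 92 are ERCC spike-in RNAs. Per the submitters' processing notes, Bowtie2 2.2.9 and RSEM 1.2.30 were used with the mm10 (GRCm38) build; the annotation release is not given in the sources used here. RSEM divides reads that match several genes between them by a model, so values of near-identical copies depend on that model. TPM keeps no read depth: the total count per cell is unknown, and the number of genes detected stands in for it. TPM also divides by transcript length, so genes of short RNAs read high from few reads. Per the deposited values, the row Rn18s-rs5 alone took 57.9% of the TPM on average, Yam1 8.73%, Gm15662 4.92% and mt-Rnr2 2.14%. Plate means of the share of Rn18s-rs5 ran from 55.3% to 61.5%, so all other genes of a cell read lower where that share is higher. ERCC rows took 2.87% to 4.98% and mitochondrial genes 2.48% to 3.32% by plate and gate.

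Each cell was given its group from its genotype label and its sorting label, and its plate and well from its title. The number in the title was read as a plate. The labels name no animal, so each genotype was counted as 1 sample, no test between genotypes was run and no p-value or standard error is printed. Plates are shown apart. Their Xist and Y-linked RNA shows that at least 2 animals contributed to each genotype, but the labels do not say how many, or which plates share an animal, so plates were not taken as independent replicates. No column was identical to another, and the highest correlation between 2 cells was 0.73 over log2(TPM + 1). No doublet caller was run, since cells were sorted singly.

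Cells with at least 1000 genes at 1 TPM or more were kept (378 of 384). Ratios were computed from mean TPM over the cells of a plate, averaged over the plates of a genotype with equal weight, with a pseudocount of 1 TPM, which understates differences of low genes. Genes averaging at least 5 TPM over the 5 plates were called measured. A gene passed the size rule in Sca-1-negative cells with a ratio of at least 2 or at most 0.5 and with no overlap between the plates of both genotypes in mean TPM and in mean log2(TPM + 1). For members of a list the ratio was 1.5. Comparisons of gates, and of Sca-1-positive cells, used a ratio of at least 2 and a difference of at least 1 in mean log2(TPM + 1). These rules describe sizes and are not tests. A cell counted as positive for a gene at 10 TPM or more and for a list with at least 3 positive members. Shares carry exact (Clopper-Pearson) 95% binomial intervals, and a share of 0 an upper limit of 3 divided by the number of cells. Both cover counting error only.

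Fixed before the data were examined were 24 gene lists (417 of 419 genes found in the table), the rules above and the rule for the genes named: the NFI family, the 10 highest and 10 lowest ratios past the size rule, and up to 4 members of each list. The 10 and 10 needed at least 20 TPM in the higher group and at least 25% positive cells there, with predicted, mitochondrial and ribosomal protein genes left out. Of each list the members past the list rule with the largest ratios were named or, where none passed, the 2 with the highest TPM; 1 gene that this rule names is not reported here. For comparisons by gate the 5 highest and 5 lowest ratios were named under the same filters. Other genes named were chosen after their values were seen, as members of a list described. List medians are given relative to the median of all measured genes and as percentiles among 10000 random lists of the same size matched on expression in 20 bins, a description of these plates.

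Alternatives chosen before the data were examined were pseudocounts of 0.1 and 10, other filters on cells (none, or 2500 genes) and genes (none, or 20 TPM), and ratios of 1.5 and 3. They also took median-of-ratios size factors per plate, removal of mitochondrial genes, removal of the highest 5% of cells per gene (rounded up to whole cells), and removal of cells with markers of other types or of the cell cycle. Further ones were matching on classes of genes detected, pooling of cells, differences of mean log2, unmatched random lists, rows C and D alone as Sca-1-negative cells, other thresholds for positive cells, and leaving out each plate. Chosen after the data were seen were removal of the ERCC rows and of the 5 most abundant rows with rescaling, the Xist plates alone, the Y plates alone, and equal weight for both kinds.

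The rule was tested on simulated data. Plates of the real sizes were drawn with replacement from all Sca-1-negative cells for the comparison of dKO with cKO, over 7019 measured genes. With no gene changed, 61 of 7010 genes passed. Then 200 genes were changed, drawn from those averaging at least 10 TPM over the pooled cells, so the rates do not cover lower genes. The rule took 40% of those changed 2-fold, 74% of those changed 3-fold and 94% of those changed 4-fold, of 50 each and none in the wrong direction. These plates carry no difference between plates or animals, so these rates leave out that spread. Splits of the real plates other than by genotype passed 38 to 138 genes, but differences by genotype and by Xist and Y-linked RNA can enter these splits. Gene positions come from the GENCODE M21 annotation of GRCm38, matched by Ensembl identifier for all 75 genes looked up. Its release may differ from that behind the table. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.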

Results

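The data are single-cell transcriptomes of hair follicle stem cells from mouse back skin at postnatal day 70, each cell sorted into its own well and amplified with the Smart-seq2 full-length protocol. Nuclear factor I (NFI) proteins are transcription factors, and the mice carried floxed Nfi alleles with Sox9-CreER, a tamoxifen-inducible recombinase expressed from the regulatory sequence of a hair follicle stem cell factor, and a YFP reporter. In the group labelled cKO both Nfix alleles and 1 Nfib allele were floxed. In the group labelled dKO both alleles of each gene were floxed. These are the genotype labels, although the series text names the group with 1 floxed Nfib allele NFIB-cKO. Where the floxed alleles recombined, which was not checked, the comparison asks what the loss of the last Nfib allele adds to the loss of Nfix. All cells were sorted as viable, integrin α6-positive and YFP-positive, and either negative or positive for Sca-1 (the Ly6a product), a surface protein that is low on bulge stem cells and high on the upper follicle and epidermis. The cells lie on 5 plates. After 6 cells with fewer than 1000 genes were left out, 378 remained. The Sca-1-negative gate held 183 cKO cells on 3 plates and 154 dKO cells on 2 plates. The Sca-1-positive gate held 22 cKO cells on plate 3 and 19 dKO cells on plate 2. The median number of genes at 1 TPM or more was 4805, 4963 and 5044 on the cKO plates and 5199 and 5189 on the dKO plates, and 4808 and 4770 in the Sca-1-positive cells. The labels name no animal and do not say which plates share one, so each genotype was counted as 1 sample. No test between genotypes was made, and values are given per plate, which shows technical and animal differences together.

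The plates fell into 2 kinds by sex-linked RNA, although the labels give all cells as male. Xist, the RNA that coats the inactive X chromosome of female cells, averaged 51.4 TPM on cKO plate 1, 59.8 TPM on cKO plate 2 and 44.5 TPM on dKO plate 1. It was 0.00338 TPM on cKO plate 3 and 0.102 TPM on dKO plate 2. The summed TPM of the 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty averaged 41.7 on cKO plate 3 and 34.1 on dKO plate 2, against 0.978, 0.906 and 0.578 on the plates with Xist. No kept cell reached 10 TPM for both. Each genotype therefore had plates of both kinds, and comparisons below are given for all plates and within each kind: dKO plate 1 against cKO plates 1 and 2 (the Xist plates), and dKO plate 2 against cKO plate 3 (the Y plates).

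**Figure D1:**
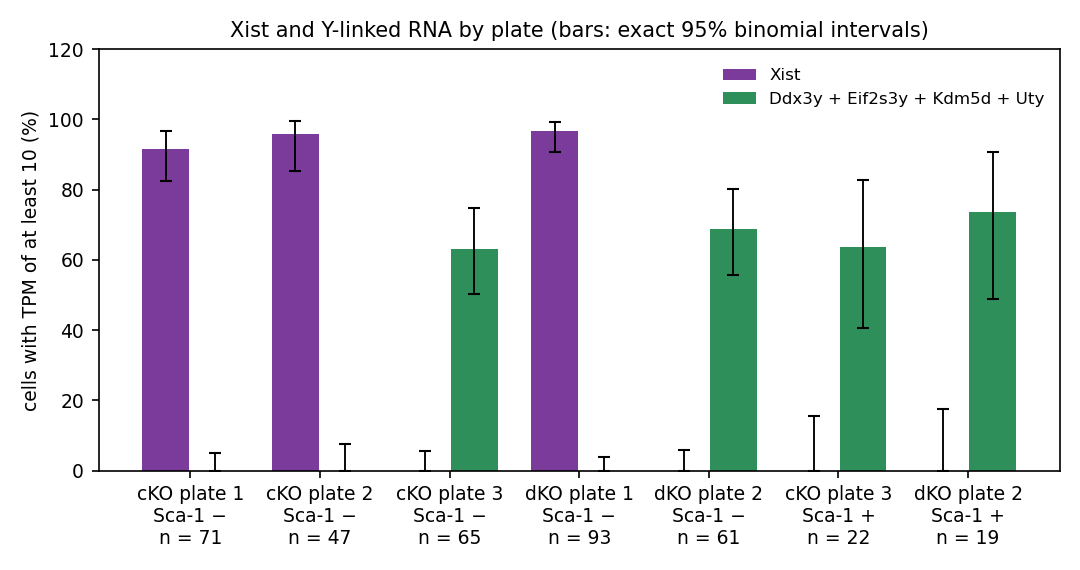
Share of cells (%) with at least 10 TPM of Xist (purple) or of the summed Y-linked genes (green), by plate and gate, with exact 95% binomial intervals that cover counting error only. Xist was found in 91.5%, 95.7% and 96.8% of the cells of cKO plates 1 and 2 and dKO plate 1 and in 0 cells of the other plates, where Y-linked RNA was found in 63.1% to 73.7% of cells.

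The targeted genes were read in both genotypes. Nfix (chromosome 8, 84699876 to 84800344, minus strand, GRCm38) averaged 46.7, 48.0 and 43.7 TPM on the cKO plates and 29.6 and 32.3 TPM on the dKO plates, although it was floxed on both alleles in both groups. Nfib (chromosome 4, 82290173 to 82705750, minus strand) averaged 80.4, 72.8 and 67.1 TPM on the cKO plates and 58.4 and 90.4 TPM on the dKO plates, a ratio of 1.01. At least 10 TPM of Nfib was found in 87.1% (95% exact interval 78.5% to 93.2%) and 98.4% (91.2% to 99.96%) of dKO cells. TPM per gene does not separate a transcript that lacks the floxed exon from an intact transcript, so these values neither check nor contradict the genotype labels. The family members that were not targeted stood at 63.1 TPM in cKO and 76.3 TPM in dKO for Nfia, and at 44.6 and 33.6 TPM for Nfic.

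In Sca-1-negative cells, the dKO plates read lower for Acsbg1, Cyp4b1 and the bulge keratin Krt15, and higher for Tnc, Tgfb2 and Bgn. Acsbg1, a fatty acyl-CoA synthetase, averaged 52.1 TPM in cKO and 3.97 TPM in dKO, a 10.7-fold difference. The cytochrome P450 gene Cyp4b1 averaged 32.3 TPM in cKO and 5.16 TPM in dKO, 5.4-fold lower, and was found in 45.1%, 55.3% and 61.5% of cKO cells but 14.0% and 11.5% of dKO cells by plate. Krt15 averaged 566 TPM in cKO and 233 TPM in dKO, with 515, 742 and 440.3 TPM on the cKO plates and 182 and 284 TPM on the dKO plates. In the other direction Tnc, which encodes the matrix protein tenascin C, averaged 6.12 TPM in cKO and 32.7 TPM in dKO, 4.73-fold higher. Tgfb2, a TGF-β ligand, averaged 11.1 and 37.3 TPM, and Bgn, which encodes the proteoglycan biglycan, 15.9 and 52.6 TPM.

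Of 7103 genes that averaged at least 5 TPM over the 5 plates, 45 stood at least 2-fold higher in dKO with both dKO plates above all 3 cKO plates, and 87 stood at least 2-fold lower. The 10 with the highest ratios that also met the filters on level and detection were BC100530 (6.05-fold), Stfa3 (5.82-fold), Tnc, Synpo2 (4.73-fold), Cyp2b19 (4.45-fold), Tnfrsf11b (3.72-fold), Tgfb2 (3.17-fold), Bgn (3.16-fold), Robo2 (2.74-fold) and Krtdap (2.61-fold). Stfa3 and BC100530 belong to the stefin A family of cysteine protease inhibitors, whose near-identical copies share reads, so their separate values are uncertain. BC100530 rested mainly on dKO plate 1, with 80.9 TPM there, 23.8 TPM on dKO plate 2 and 12.7, 7.38 and 3.33 TPM on the cKO plates. Tnfrsf11b encodes osteoprotegerin, a decoy receptor, Robo2 a receptor for Slit ligands, and Krtdap a protein of differentiating keratinocytes. Krtdap averaged 68.7, 20.4 and 120.4 TPM on the cKO plates and 180.2 and 188 TPM on the dKO plates. Cyp2b19, a cytochrome P450 of differentiating keratinocytes from a family of similar genes, rested mainly on dKO plate 2, with 59.1 TPM there, 10.6 TPM on dKO plate 1 and 10.1 TPM on cKO plate 3.

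The 10 genes with the lowest ratios were Acsbg1, Cyp4b1, Tgm5 (4.08-fold lower), Nbl1 (2.96-fold), Ackr4 (2.81-fold), Slco2b1 (2.6-fold), Rbms3 (2.46-fold), Myh14 (2.45-fold), Nfkbiz (2.45-fold) and Krt15 (2.42-fold). Tgm5, a transglutaminase that cross-links the cornified envelope, averaged 56.6, 38.2 and 36.9 TPM on the cKO plates and 8.58 and 11.4 TPM on the dKO plates. Nbl1 encodes a secreted BMP antagonist, Ackr4 an atypical chemokine receptor, Slco2b1 an organic anion transporter and Nfkbiz a nuclear cofactor of NF-κB. Nfkbiz was barely apart, with 12.2 TPM on dKO plate 1 and 12.3 TPM on cKO plate 3. The rule that chose these 20 genes requires the same direction on the Xist plates and on the Y plates, so only the sizes are compared here. Krt15 differed more on the Xist plates (log2 ratio -1.79) than on the Y plates (-0.63), and so did Nbl1 (-2.41 and -0.44), whereas Acsbg1 (-3.22 and -3.58) and Cyp4b1 (-2.49 and -2.31) were close. Acsbg1 lies on chromosome 9 (54604877 to 54661870), Cyp4b1 on chromosome 4 (115624725 to 115647723), Krt15 on chromosome 11 (100131758 to 100135928), Tnc on chromosome 4 (63959785 to 64047015) and Tgfb2 on chromosome 1 (186622792 to 186705989), all on the minus strand of GRCm38.

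**Figure D2:**
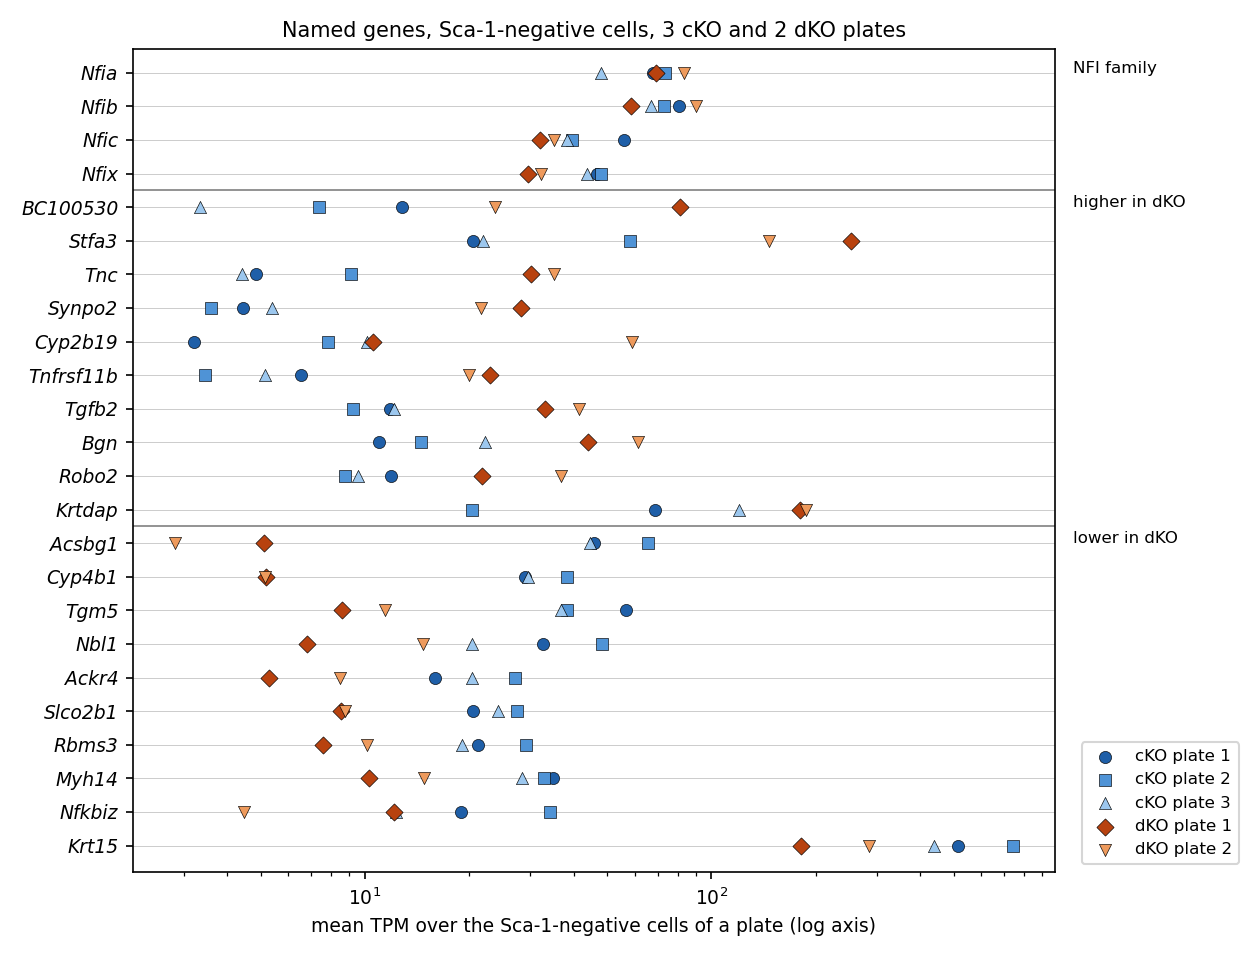
Mean TPM (log axis) over the Sca-1-negative cells of each plate for the 4 NFI genes and for the 10 genes with the highest and the 10 with the lowest ratio of dKO to cKO. Blue symbols are the 3 cKO plates and orange symbols the 2 dKO plates. For the 20 genes below the NFI family the orange symbols lie on 1 side of all blue symbols, from 5.12 and 2.82 TPM against 44.7 TPM or more for Acsbg1 to 12.2 against 12.3 TPM for the nearest plates of Nfkbiz.

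The count itself was not the largest over the splits of the 5 plates into 3 and 2. Grouping cKO plates 1 and 2 against the other 3 plates gave 138 genes by the same rule, against 132 for the genotypes. That split keeps both dKO plates together and sets them against Xist plates alone, so genotype and kind can enter it. The split by kind gave 127, and the remaining splits gave 38 to 80. The splits therefore give no spread between plates that is free of genotype and kind. In simulated plates drawn from the pooled cells, which carry no difference between plates, 61 of 7010 genes passed. The plates of both genotypes were apart on both scales in 11.95% of the measured genes, against a mean of 10.1% and a highest value of 12.9% over the 10 splits of the plates, the real split included. On 1 scale alone, chance parts the plates of 20% of genes. The median of all genes was -0.12 (log2) and moved to -0.02 with size factors and to -0.003 after the ERCC rows and the 5 most abundant rows were removed. The higher and lower counts then became 53 and 62, and 250 and 200 among 12269 measured genes. Without dKO plate 1 the counts were 120 and 246, without dKO plate 2 they were 53 and 192, without cKO plate 1 they were 84 and 123, and without cKO plate 3 they were 71 and 187. Across the genes, the log2 ratios of the Xist plates and of the Y plates, which share no library, correlated at r = 0.14 (Spearman rho 0.15), where genes are not independent replicates. Over the 666 genes that averaged at least 50 TPM it was r = 0.34. The log2 ratio of cKO plate 2 to cKO plate 1 correlated with that of the Y plates at r = -0.004. Relative to their medians, 37 genes were at least 2-fold higher in dKO in both, against 4.55 for independent lists, and 42 were at least 2-fold lower in both, against 7.38. Opposite differences of that size were found for 11 and 18 genes, against 4.24 and 7.91 for independent lists.

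Gene lists written before the data were examined are described by the median log2 ratio of their measured members relative to all genes, and by its percentile among 10000 random lists matched on expression. Immediate early genes, which respond within minutes to stimulation and tissue dissociation, stood lowest of the lists with at least 5 measured members, with a median of -0.65 over 19 members (percentile 0.0). Only Klf4 was at least 1.5-fold apart on all plates, with 49.5 TPM in cKO and 30.6 TPM in dKO. Plates of 1 genotype but of different kinds differed more than the genotypes for this list. The median of dKO plate 2 was -1.59 relative to dKO plate 1, and that of cKO plate 3 was -1.21 relative to cKO plate 2. Plates of the same kind, cKO plate 2 relative to cKO plate 1, stood at 0.28. Between the genotypes the list was -0.41 on the Xist plates (percentile 0.01) and -0.83 on the Y plates (percentile 0.0). Btg2, a member of this list and of the p53 list, averaged 54.2, 69.9 and 16.8 TPM on the cKO plates and 38.5 and 7.19 TPM on the dKO plates.

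The bulge stem cell list had a median of -0.11 over 18 measured members (percentile 8.2). Krt15 was lower, Cd200, a bulge surface marker, was higher (25.3 TPM in cKO and 42.6 TPM in dKO), and the other 16 members were not at least 1.5-fold apart on all plates. The list went opposite ways within the kinds of plates, at -0.39 on the Xist plates (percentile 0.0) and 0.28 on the Y plates (percentile 99.8). Cd34, the classical surface marker of bulge cells, which the naming rule took from the comparison by Sca-1 given further on, averaged 99.8, 81.5 and 44.3 TPM on the cKO plates and 26.1 and 48.4 TPM on the dKO plates. Of the 11 measured genes of quiescence and BMP response, Wif1, a secreted WNT inhibitor (3.27 TPM in cKO and 20.04 TPM in dKO), and Tgfb2 were higher and Grem1, a BMP antagonist (13.1 and 3.65 TPM), was lower, with a list median of -0.20 (percentile 3.44). Within the kinds it was -0.05 on the Xist plates (percentile 38.5) and -0.11 on the Y plates (percentile 20.6), and over the alternatives its percentile ran from 0.585 to 88.8. The upper follicle list had a median of -0.26 over 14 members (percentile 0.24), with Lgr6, a stem cell receptor of the upper follicle, at 18.7 TPM in cKO and 7.53 TPM in dKO. Its median turned to 0.09 (percentile 85.8) with genes of at least 20 TPM alone. It was -0.08 on the Xist plates (percentile 19.8) and -0.27 on the Y plates (percentile 0.94). It was -0.09 without cKO plate 3 (percentile 21.99), -0.12 without dKO plate 1 (percentile 17.1) and -0.02 without cells carrying cell cycle genes (percentile 35.8). Without cKO plate 1, cKO plate 2 or dKO plate 2 it stayed at -0.34, -0.30 and -0.30 (percentile 0.05 each). The low percentile thus depended on cKO plate 3, on dKO plate 1 and on the cells kept. The cell cycle list had a median of -0.28 over 14 members (percentile 0.66), with no member apart on all plates. Its median was 0.07 on the Xist plates and -0.48 on the Y plates. The named members Ccnd2 and Ccnd1 averaged 98.6 and 25.2 TPM in cKO and 65.4 and 29.0 TPM in dKO. Single plates decided this direction: the median was 0.10 without cKO plate 1 and 0.15 without dKO plate 2.

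Among wound and stress keratinocyte genes the median was -0.13 over 11 members, but Krt17, a keratin of the outer root sheath and of activated keratinocytes, stood at 443 TPM in cKO and 814 TPM in dKO. Stfa3 was also higher, and the transcription factor Klf6 was lower (27.0 and 14.9 TPM). Differentiated epidermis had a median of 0.11 over 11 members with Krtdap higher, and it was 0.24 on the Xist plates and -0.18 on the Y plates. Lipid and cholesterol synthesis had a median of 0.11 over 15 members. In that list Scd2, a fatty acid desaturase (3.69 and 10.4 TPM), and Fdps, an enzyme of the mevalonate pathway (8.08 and 16.2 TPM), were higher. The sebaceous gland list had a median of 0.11 over 9 members, with Acsbg1 its only member apart. Interferon response and MHC genes had a median of -0.10 over 12 members. YAP and TEAD targets had a median of -0.05 over 10 members, with Ajuba lower (33.0 and 20.8 TPM). It was -0.17 on the Xist plates (percentile 9.59) and 0.30 on the Y plates (percentile 97.8). Cytokines and chemokines had a median of 0.18 over 8 members, with Nfkbiz lower. Hemidesmosome and basement membrane genes had a median of -0.11 over 17 members, with Tnc their only member apart, and -0.16 on the Xist plates and 0.13 on the Y plates (percentile 92.7). The sign also differed between the kinds for the sebaceous gland list (-0.04 and 0.07), the basal keratinocyte list (0.03 and -0.10) and the p53 and senescence list (-0.07 and 0.08).

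Basal keratinocyte genes were close in both genotypes, with a median of -0.02 over 18 members, none of them apart. Krt5 averaged 901 TPM in cKO and 825 TPM in dKO, and Krt14 averaged 869.9 and 644 TPM. Hair germ and hair shaft lineages had a median of 0.21 over 7 members, none of them apart, with Gata3 at 62.2 and 55.6 TPM and Axin2 at 22.6 and 27.6 TPM. The p53 and senescence list had a median of 0.08 over 10 members, none of them apart, with Cdkn1a at 75.5 and 43.7 TPM. The RNA quality list of mitochondrial and nuclear RNAs had a median of 0.15 over 10 members (percentile 97.6), with Malat1 at 1473 and 1585 TPM and mt-Co1 at 1258 and 1364 TPM. In the lists of other cell types few genes were measured. Of the fibroblast list only Col1a1 was (2.43 TPM in cKO and 17.8 TPM in dKO), and of the melanocyte list Gpnmb (3.81 and 18.6 TPM) and Mitf. Of the immune list it was Cd74 (20.1 and 6.25 TPM), of the endothelial and mural list Cspg4 (17.2 and 15.5 TPM), and of the Schwann and nerve list Erbb3 (14.4 and 10.7 TPM) and L1cam (7.36 and 3.21 TPM). No Merkel cell or erythroid gene was. At least 3 markers of another type were found in 4 of 378 cells for immune cells, in 1 cell for Schwann and nerve cells, and in 0 cells for each other type.

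**Figure D3:**
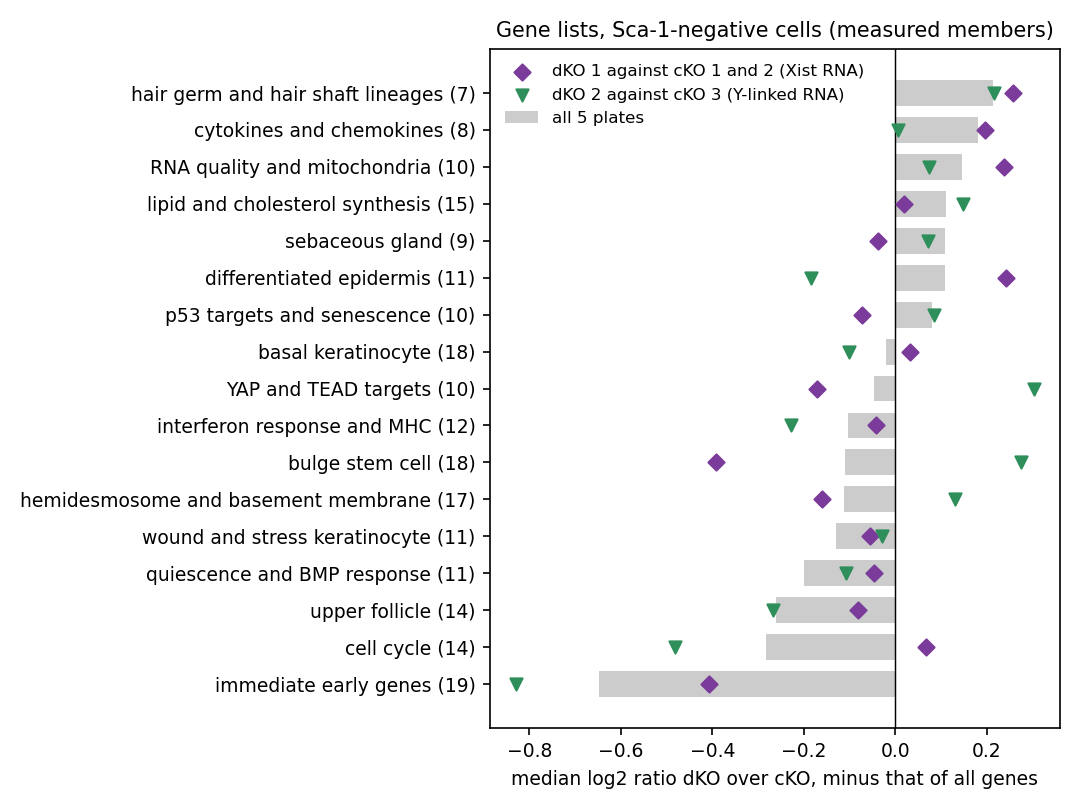
Median log2 ratio of dKO to cKO of each list with at least 5 measured members, relative to the median of all genes, in Sca-1-negative cells. Bars are all 5 plates, diamonds the Xist plates and triangles the Y plates, and the number of measured members stands in parentheses. Immediate early genes lie lowest at -0.65, and the bulge stem cell list lies at -0.39 on the Xist plates and at 0.28 on the Y plates.

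Shares of positive cells were counted per plate. Krtdap at 10 TPM or more was found in 23.9% (95% exact interval 14.6% to 35.5%), 17.0% (7.6% to 30.8%) and 29.2% (18.6% to 41.8%) of cKO cells and in 54.8% (44.2% to 65.2%) and 47.5% (34.6% to 60.7%) of dKO cells. Tnc was found in 12.7%, 17.0% and 10.8% of cKO cells and in 26.9% and 27.9% of dKO cells. Krt15 was found in 92.96%, 100% and 92.3% of cKO cells and in 81.7% and 85.2% of dKO cells. Cd34 was found in 32.4%, 27.7% and 24.6% of cKO cells and in 24.7% and 26.2% of dKO cells, a difference within the intervals (16.4% to 34.8% for dKO plate 1). Cells with at least 3 cell cycle genes made up 47.9%, 31.9% and 55.4% of the cKO plates and 48.4% and 45.9% of the dKO plates. The intervals cover counting error only.

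Sca-1-positive cells were compared with Sca-1-negative cells of the same plate, cKO plate 3 and dKO plate 2. In both genotypes the Sca-1-positive cells read far lower for most of the bulge list and higher for Krt14 and Gata3. Of the bulge stem cell list, 12 of 16 measured members were at least 2-fold lower on the cKO plate and 13 of 17 on the dKO plate, and none was higher. Against rows C and D alone as Sca-1-negative cells, 7 (cKO) and 14 (dKO) members were lower. Krt15 was not among the 12 and 13, with 440.3 TPM in Sca-1-negative and 436 TPM in Sca-1-positive cKO cells, and 284 and 421 TPM in dKO cells. Lgr5, a receptor of bulge and hair germ stem cells, averaged 42.1 TPM in Sca-1-negative and 0.015 TPM in Sca-1-positive cKO cells, and 44.0 and 0.0247 TPM in dKO cells. Cd34 averaged 44.3 and 0.362 TPM in cKO and 48.4 and 0.165 TPM in dKO, and reached 10 TPM in 0 of 22 and 0 of 19 Sca-1-positive cells, which allows shares of up to 13.6% and 15.8%. Krt14, a keratin of basal keratinocytes, stood 2.84-fold higher in Sca-1-positive cKO cells (2294 against 806 TPM) and 4.88-fold higher in dKO cells (2821 against 577 TPM). The transcription factor Gata3 was 2.98-fold and 2.77-fold higher. Most members of their lists did not follow. Of 18 basal keratinocyte genes 2 were higher and 1 lower on the cKO plate (list percentile 48.2), and 3 and 2 on the dKO plate (94.9). Of 7 hair germ and hair shaft genes 1 was higher and 1 lower on each plate, with list medians of -0.14 and -0.28.

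By the size rule for 2 gates, 199 genes were higher and 385 lower in the Sca-1-positive cells of the cKO plate, and 280 were higher and 682 lower on the dKO plate. The excess of lower genes depended on scaling: the medians of all genes were -0.15 and -0.30, and size factors gave 303 higher and 274 lower genes on the cKO plate and 459 and 443 on the dKO plate. Of 5829 genes measured on both plates, 89 were higher on both (7.28 for independent lists), 177 were lower on both (37.3 for independent lists) and 1 went opposite ways. The log2 ratios of both plates correlated across genes at r = 0.47 (Spearman rho 0.37). On the cKO plate the highest ratios were those of Il1r2, a decoy receptor for interleukin-1 (0.13 and 32.2 TPM), Ptges, a prostaglandin E synthase (0.0638 and 26.8 TPM), the alarmin Il33 (0.454 and 25.3 TPM), the semaphorin Sema3d and the calmodulin-like gene Calm5. On the dKO plate they were those of Ly6c1 and Bmp4, both listed at 0 in all 61 Sca-1-negative cells and at 49.5 and 24.5 TPM in Sca-1-positive cells, Sprr2a2, of a family of near-identical cornified envelope genes, Gdpd2, and again Il1r2 (0.429 and 28.7 TPM). The lowest ratios on the cKO plate were those of Tgm5, listed at 0 in all 22 Sca-1-positive cells against 36.9 TPM, Calml3 (133 and 4.26 TPM), Bnc2, the adhesion molecule Alcam and Iqsec1. On the dKO plate Ctgf, Bgn and Cd200 were listed at 0 in all 19 Sca-1-positive cells against 61.7, 61.2 and 43.3 TPM in Sca-1-negative cells, followed by Cd34 and Calml3 (169 and 3.1 TPM).

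Upper follicle genes were also lower in Sca-1-positive cells, 7 of 14 on the cKO plate and 7 of 12 on the dKO plate, with 1 and 2 members higher. Ly6a, which encodes the protein used to sort, was left out. Krt79 averaged 171 and 45.2 TPM in cKO and 92.4 and 5.12 TPM in dKO. Immediate early genes were higher for 3 of 19 members on the cKO plate and for 14 of 19 on the dKO plate. Atf3 was 2.7-fold and 9.48-fold higher. Fos averaged 277 TPM in Sca-1-negative and 554 TPM in Sca-1-positive cKO cells, and 151 and 949 TPM in dKO cells. On the dKO plate 1 member, Ier3, was lower. Whether this list differed between the genotypes was not tested. Quiescence and BMP response genes were lower for 4 and 5 of 10 members. Cytokine and chemokine genes were higher for 3 of 10 and 3 of 9 members. The NF-κB inhibitor genes Nfkbia and Tnfaip3 were among the higher members on both plates.

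Both gates lay in different rows of their plates, so rows A and B were compared with rows C to H on the 3 plates sorted for Sca-1-negative cells alone. There the same rule gave 705 higher and 221 lower genes on cKO plate 1 (11 cells in rows A and B), 244 and 247 on cKO plate 2 (16 cells) and 83 and 56 on dKO plate 1 (23 cells). The higher counts by gate (199 and 280) lay within this range, but its top of 705 came from cKO plate 1. In rows A and B there, 6 of 11 cells carried at least 8 cell cycle genes. Their median number of genes was 5653, against 4759.5 in rows C to H. Against the 244 and 83 of cKO plate 2 and dKO plate 1, the 199 lay between them and the 280 above both. The lower counts (385 and 682) lay above it in deposited TPM, at other numbers of cells; the rows were not run with size factors, which lowered the counts by gate to 274 and 443. Of the bulge list 2 of 19, 2 of 19 and 1 of 17 members were lower in these rows, and of the immediate early genes 0 of 19, 0 of 20 and 1 of 19 were higher. The list median of the immediate early genes was -0.14, -0.26 and 0.41 by row, against 0.60 (cKO) and 2.33 (dKO) by gate. The 0.41 of dKO plate 1 (percentile 99.99) came near the gate value of the cKO plate (percentile 99.97). Of the quiescence and BMP response genes 0, 7 and 0 of 10 members were lower, so the 4 and 5 by gate lay within this range. The wound and stress list stood at 0.86 and 0.72 by gate and at 0.21, -0.25 and 1.04 by row. Interferon response and MHC genes stood at 0.55 and 0.74 by gate and at 0.34, 0.26 and 0.02 by row. The RNA quality list stood at -0.07 and -0.18 by gate and at -0.23, 0.12 and 0.14 by row.

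**Figure D4:**
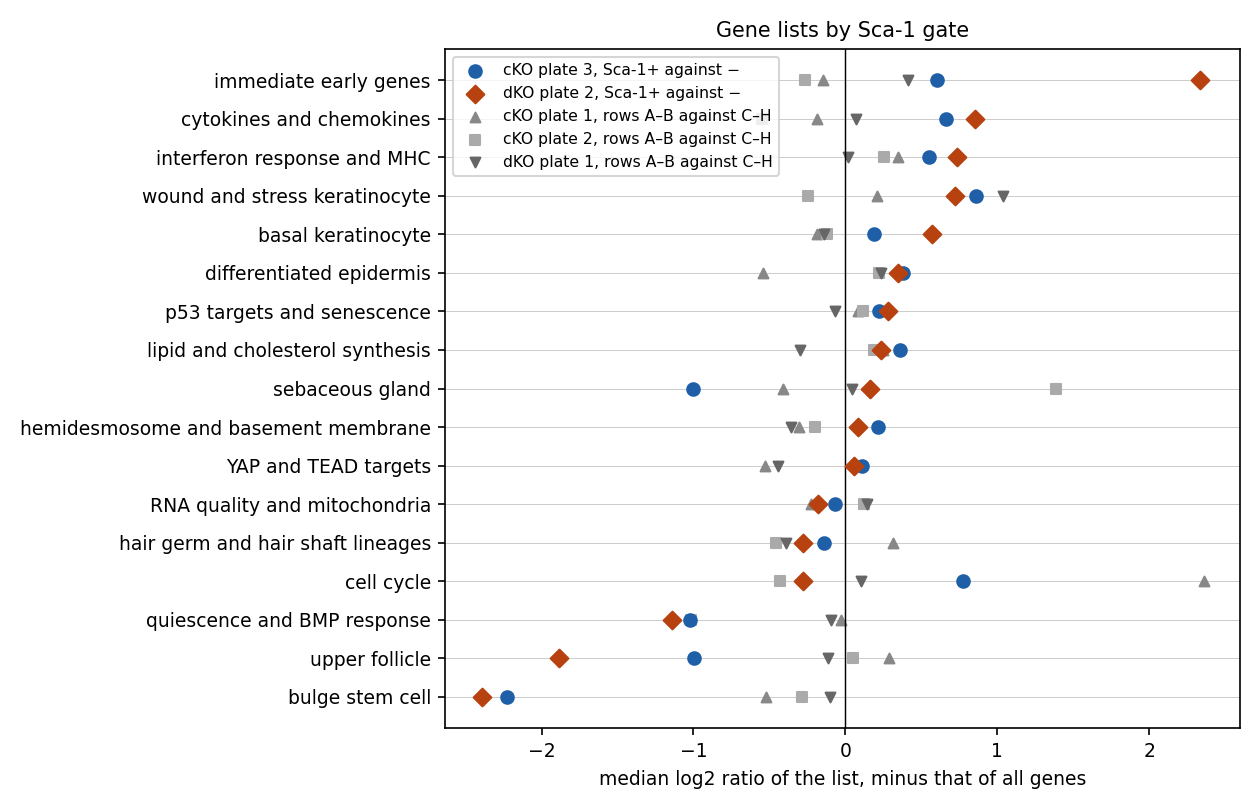
Median log2 ratio of each list relative to all genes for Sca-1-positive against Sca-1-negative cells of cKO plate 3 (blue circles) and dKO plate 2 (orange diamonds). Grey symbols are rows A and B against rows C to H on the 3 plates with 1 gate. The bulge stem cell list lies at -2.23 and -2.39 by gate and between -0.52 and -0.10 by row, and the cell cycle list lies at 2.36 in the rows of cKO plate 1. For quiescence and BMP response the grey square of cKO plate 2 lies behind the blue circle, both at -1.02.

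Within the Sca-1-positive gate, the dKO cells were compared with the cKO cells, with 1 plate each and no replicate check. Cell cycle genes stood lower in dKO, with a list median of -1.14 over 12 members (percentile 0.0), of which only Mcm4 passed the rule. At least 3 of its genes were positive in 14 of 22 cKO and 9 of 19 dKO cells. Few cells carried many of them: at least 8 were positive in 4 of 22 cKO and 1 of 19 dKO cells. Rows of 1 gate on cKO plate 1 differed by 2.36 for this list. The RNA quality list stood at -0.18 (percentile 1.08), with mt-Co2 lower. Immediate early genes stood higher, with a median of 0.83 over 19 members (percentile 100), of which Btg2 (28.3 TPM in cKO and 66.2 TPM in dKO) and Socs3 (27.7 and 64.6 TPM) passed. In the Sca-1-negative cells of the same plates this list stood lower in dKO, at -0.83. Cytokines and chemokines stood at 0.62 over 9 members (percentile 99.5), none of them past the rule. The bulge list stood at 0.03 over 7 members (percentile 47.6). In all, 183 genes were higher and 245 lower in dKO, a balance that turned to 247 and 220 with size factors. Without the highest 5% of cells per gene it was 320 and 124. That 5% was rounded up to whole cells, which took a larger share of the 22 cKO than of the 19 dKO cells. Such unequal removal by itself raises the ratios of dKO to cKO, so this turn is not a result about the genotypes. The highest ratios were those of BC100530 (1.76 TPM in cKO and 103 TPM in dKO), Ly6c1 (5.07 and 49.5 TPM), Lins, Ccdc50 and Calm4 (9.41 and 51.0 TPM). The lowest were those of the histone gene Hist2h3b (339 and 15.8 TPM), which shares reads with near-identical histone copies, Trex1, an exonuclease (20.5 and 1.63 TPM), the short RNA gene AC122804.1, Ap1m1 and Unkl. With cells carrying at least 3 cell cycle genes left out, the counts became 626 and 746.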

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

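The tests of plate differences, genotype and fibroblast RNA and the count over plate splits were chosen after the results were seen; those on cells with very high values and on genes detected were set before their results.

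Xist RNA was read on 3 plates labelled male, at 51.4 TPM on cKO plate 1, 59.8 TPM on cKO plate 2 and 44.5 TPM on dKO plate 1. The kinds of plates are thus not balanced between the genotypes and enter the comparison of all plates. Xist was found in 91.5%, 95.7% and 96.8% of the cells of these 3 plates, and no cell there reached 10 TPM of Y-linked RNA. These values argue against the male label for these plates.

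The bulge stem cell list went opposite ways within the kinds of plates, a difference that was not tested: -0.34 for dKO plate 1 against cKO plate 1, -0.31 for dKO plate 1 against cKO plate 2, and 0.28 for dKO plate 2 against cKO plate 3 (log2 relative to all genes). A few cells with very high values do not account for most of it, since the gap between the kinds was 0.67 with all cells and 0.59 with the highest 5% of cells left out per gene. Different numbers of genes detected do not either, with a gap of 0.52 when plates were matched on them. A part is not excluded. Matching moved the Xist plates from -0.39 to -0.21 and the Y plates to 0.30. Leaving out the highest 5% moved them to -0.42 and 0.17 (percentile 94.9 on the Y plates). Without the ERCC rows and the 5 most abundant rows they stood at -0.33 and 0.14 (percentile 89.5 on the Y plates). Plates of 1 genotype but of different kinds differed as much, with cKO plate 3 at -0.38 relative to cKO plate 1 and dKO plate 2 at 0.33 relative to dKO plate 1. Such pairs are part of the same gap, so they cannot decide whether differences between plates account for the pattern. The only pair of 1 genotype and 1 kind, cKO plate 2 relative to cKO plate 1, stood at -0.06, and 1 pair does not give the spread between plates. Sex, animal and plate stay open and untested, since each kind has 1 dKO plate.

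In Sca-1-negative cells, immediate early genes stood at -0.65 in dKO relative to all genes. Differences between plates of 1 genotype, which could come from the time between dissection and lysis, were larger, up to -1.59 for dKO plate 2 relative to dKO plate 1. The list was lower in dKO for 5 of the 6 pairs of plates, and 0.79 higher for dKO plate 1 against cKO plate 3. The -1.59 and the 0.79 each compare plates of different kinds. Within the kinds the list was lower in dKO, at -0.41 on the Xist plates (percentile 0.01) and -0.83 on the Y plates (percentile 0.0). The only pair of 1 genotype and 1 kind, cKO plate 2 relative to cKO plate 1, stood at 0.28. In the Sca-1-positive cells of the Y plates the list went the other way, at 0.83 (percentile 100). A part due to genotype cannot be told apart from animal and plate, because each kind has 1 dKO plate.

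The matrix genes Tnc, Bgn and Col1a1, picked after their values were seen, stood higher in dKO. No list of extracellular matrix genes was tested, and the hemidesmosome and basement membrane list, with only Tnc apart, stood at -0.16 on the Xist plates and 0.13 on the Y plates. RNA from fibroblasts is argued against: Col1a1 averaged 17.8 TPM in dKO, whereas the highest of the other 9 fibroblast genes, Mfap5, averaged 0.189 TPM, and Col1a2, whose product pairs with that of Col1a1, was listed at 0. The integrin α6 and YFP sort would also remove fibroblasts. A difference in the follicle cells themselves, by genotype, animal or plate, stays open as a hypothesis.

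The count of 132 genes past the size rule was reached or passed by 2 of the 10 splits of the 5 plates into 3 and 2, the real split included. The highest other split, cKO plates 1 and 2 against the rest, gave 138, but it keeps both dKO plates together, so genotype can enter it. The 10 splits are too few for a share under 0.05. The split by Xist and Y-linked RNA gave 127, and the remaining splits gave 38 to 80. Within the Xist plates 71 genes were higher and 303 lower, and within the Y plates 308 and 241, with fewer plates to part. The medians of all genes were -0.23 on the Xist plates and 0.04 on the Y plates, so a shift of all genes enters these counts. Relative to these medians, and by the 2-fold ratio alone, 115 genes were higher and 200 lower on the Xist plates, and 281 and 262 on the Y plates.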

How the results depend on the processing

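The alternatives changed 1 choice at a time. The direction of the 20 genes with the highest and lowest ratios was kept in all 420 values under alternatives, with 0 reversed. They were chosen for plates that do not overlap, so leaving out plates, either kind of plates alone, equal weight, pooling, other pseudocounts and mean log2 could not reverse them. Only the alternatives on cells and on scaling could, and these did not. Not all of them still passed the size rule: of 10 higher and 10 lower genes, 9 and 5 with a pseudocount of 10, 9 and 5 by mean log2, 7 and 8 without cells carrying cell cycle genes, 5 and 6 at 20 TPM, 8 and 3 at a ratio of 3, and 9 and 6 on the Y plates alone. Under each other alternative at least 9 of each 10 passed. Acsbg1 ranged from -3.80 to -1.59 (log2 ratio), Cyp4b1 from -3.23 to -1.48, Krt15 from -1.86 to -0.63, Tnc from 0.99 to 2.74 and Tgfb2 from 0.96 to 2.91. Over the 51 named genes of the Sca-1-negative comparison, 975 of 1071 values moved by less than the spread between plates and 96 by more. In Sca-1-negative cells the immediate early genes stayed lower in dKO throughout, at percentiles of 0.0 to 1.815, but by very different amounts. Their median of -0.65 became -1.71 without dKO plate 1, -0.97 without cKO plate 3, -0.36 without cKO plate 2 and -0.15 without dKO plate 2. In the Sca-1-positive cells of the Y plates the list went the other way, at 0.83 (percentile 100). Of the counts and list medians that answer a comparison, 234 values stayed within their limits (for a list, the spread between plates), 69 moved and 5 reversed; those that moved or reversed follow, with higher before lower. The spread between plates is wide: the bulge list, at -0.11, counts as within it although its sign changed to 0.053 (percentile 76.95) with matching on genes detected, 0.026 without cKO plate 1 and 0.10 without dKO plate 1. Apart from the reasons given, the cause was not tested.

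Chosen before the data were seen: a pseudocount of 10 left 20 and 17 genes of 45 and 87 in Sca-1-negative cells, since it shrinks ratios of low genes. It left 50 and 79 between genotypes in Sca-1-positive cells, 77 and 156 by gate in cKO and 148 and 306 by gate in dKO. A minimum of 20 TPM left fewer genes to measure: 13 and 21, 54 and 40, 64 and 103, and 123 and 170. It left 5 bulge genes lower by gate in cKO and 6 in dKO, and reversed the upper follicle list to 0.0896. No filter on low values gave 183 and 240 genes in Sca-1-negative cells, a ratio of 1.5 gave 125 and 281, and a ratio of 3 gave 18 and 22, by construction.

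With cells carrying cell cycle genes left out, 71 and 162 genes passed in Sca-1-negative cells, 626 and 746 between genotypes in Sca-1-positive cells and 502 and 700 by gate in cKO, and 464 were higher by gate in dKO. Fewer cells were left. The cell cycle list, on which the cells were chosen, reversed to 0.20. Differences of mean log2(TPM + 1) gave 20 lower genes in Sca-1-negative cells, 369 and 374 between genotypes in Sca-1-positive cells, and 454 (cKO) and 486 (dKO) higher by gate. Without the highest 5% of cells, 320 and 124 genes passed between genotypes in Sca-1-positive cells. Rounding up to whole cells took a larger share of cKO than of dKO cells there, which by itself raises the ratios. Size factors gave 303 and 274 genes by gate in cKO, against 199 and 385, and 459 and 443 by gate in dKO, against 280 and 682, so the excess of lower genes was gone. Rows C and D alone gave 337 higher genes by gate in cKO and 7 bulge genes lower. The immediate early genes higher by gate in cKO were few, 3 of 19, and became 1 with no filter on cells, 1 with rows C and D, 5 with size factors, 5 without the highest 5% of cells and 6 by mean log2.

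Chosen after seeing the data: without the ERCC rows and the 5 most abundant rows, and with the rest rescaled, 250 and 200 genes passed in Sca-1-negative cells (12269 measured). Among the 7103 genes of the main count they were 70 and 66, so most of the gain came from genes that rescaling lifted over the minimum. The other counts became 536 and 758 between genotypes in Sca-1-positive cells, 526 and 843 by gate in cKO, with 5 immediate early genes, and 604 and 1387 by gate in dKO. The Xist plates alone gave 71 and 303 genes, with the median of all genes at -0.23. They gave the bulge list at -0.39 and the cell cycle list reversed to 0.0677. The Y plates alone gave 308 and 241 genes and the bulge list at 0.28. Fewer plates have to be apart there. Equal weight for both kinds of plates left the counts at 44 and 79.

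Leaving out each plate in turn gave 53 to 120 higher and 101 to 246 lower genes, again with fewer plates to part. The bulge list ranged from -0.28 to 0.10 and the cell cycle list from -0.51 to 0.15. The latter reversed without cKO plate 1 (0.10) and without dKO plate 2 (0.15), so its direction rests on single plates.

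No paired analysis was possible because the labels name no animal, litter or day that plates of the same number share, and do not say which plates are independent animals. That limit concerns pairs by plate number. Plates were compared within kinds by Xist and Y-linked RNA instead, a grouping taken from the data. Both genotypes had both kinds, so a fit of genotype with kind as a block was possible. It was not run, since plates were not taken as independent replicates. Matching on genes detected, other ratios, pooling and leaving out plates were not run for the gates, with 22 and 19 Sca-1-positive cells on 1 plate each. TPM keeps no read depth, so the effect of depth on low genes was not assessed beyond genes detected. Genes under 5 TPM are not described.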

Other observations

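Detection in the same cells was counted for 9 of the genes that stood higher in dKO, chosen after their values were seen. Of these (Tnc, Bgn, Col1a1, Tgfb2, Gpnmb, Wif1, Robo2, Synpo2 and Tnfrsf11b), at least 4 were positive in 32 of 93 cells of dKO plate 1 and 27 of 61 cells of dKO plate 2. Independent detection would give 23.2 and 20.1 cells. On the cKO plates it was 5 of 71, 0 of 47 and 7 of 65 cells, against 1.2, 0.45 and 0.834. The cells with at least 4 did not have more genes detected on the dKO plates: their median was 5080 against 5358 for the other cells on dKO plate 1 and 4946 against 5198 on dKO plate 2. Krt15 averaged 272 TPM in them and 134 TPM in the other cells on dKO plate 1, and 380.3 and 208 TPM on dKO plate 2. On cKO plates 1 and 3, with 5 and 7 such cells, Krt15 averaged 545 and 513 TPM, and 659 and 414 TPM. Krtdap went no common way: 298 and 51.4 TPM on cKO plate 1, 11.5 and 134 TPM on cKO plate 3, 199 and 170.4 TPM on dKO plate 1, and 221 and 161 TPM on dKO plate 2.

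Of these genes, Bgn, Synpo2 and Wif1 were listed at 0 in all 22 cKO and all 19 dKO Sca-1-positive cells. The other 6 were not, with Gpnmb at 19.3 TPM in cKO and 34.7 TPM in dKO, Tnc at 11.7 and 13.8 TPM, Tgfb2 at 3.18 and 5.75 TPM, Robo2 at 2.27 and 2.98 TPM, and Tnfrsf11b at 0.095 and 0.589 TPM. Col1a1 was listed at 0 in cKO and averaged 0.00895 TPM in dKO. Acsbg1, the gene with the lowest ratio in Sca-1-negative cells, averaged 17.0 TPM in Sca-1-positive cKO cells and 23.8 TPM in Sca-1-positive dKO cells. Tgm5 and Grem1 were listed at 0 in both groups of Sca-1-positive cells.

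Cycling cells were unevenly placed on cKO plate 1. At least 8 cell cycle genes were positive in 6 of 11 cells of rows A and B and in 5 of 60 cells of rows C to H. Top2a, a topoisomerase of dividing cells, averaged 71.5 and 11.7 TPM, and Mki67 40.6 and 6.06 TPM. The median number of genes was 5653 and 4759.5. On the other plates with 1 gate, such cells were 0 of 16 against 5 of 31 (cKO plate 2) and 2 of 23 against 7 of 70 (dKO plate 1).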
